A study of Homo sapiens with 12 samples.

How the data were processed

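The series holds 12 samples of PMA-treated THP-1 cells in 4 groups, and the 10 with data analysed here are PBS replicates 2 and 3, RSV replicates 1 to 3, rhCTSC with RSV replicates 1 to 3, and rhCTSC with sivelestat and RSV replicates 1 and 2. Groups and replicate numbers come from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and mRNA libraries were sequenced on an Illumina NovaSeq X Plus. Per the submitters' processing notes the genome build was hg38. The aligner, the quantifier and the annotation release are not given in the sources used here, nor is whether the library kit keeps strand.

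The deposited values are TPM, length-corrected shares of the transcripts, per the file headers, with 1 value per gene and library for 20344 Ensembl gene identifiers. Each library sums to 1000000, so a gene's TPM is a share: where a few transcripts take much of the total, as IL1B does in infected cells, all others are lowered. The 10 most abundant genes held 13.1% to 19.6% of the total. TPM keeps no read counts, so the depth of each library is unknown, and no count model, counting interval or detection floor was computed. A value of 0 means only that the gene is listed at 0. No 2 libraries held identical values (0 pairs). Symbols were found for 20304 identifiers in the gene name table supplied with the reference. Coordinates are those of GENCODE release 29 (GRCh38), counted from 1.

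Genes with a TPM of at least 1 in at least 2 libraries were tested, 12284 in all, on log2(TPM + 1). Fold changes are on that scale, which understates the change of low genes. A linear model with 1 mean per group was fitted to all 10 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, so that the 4 groups share 1 estimate of the spread (6 residual degrees of freedom and 4.27 prior ones). Comparisons were RSV against PBS, rhCTSC with RSV against RSV, and the sivelestat group against each of rhCTSC with RSV and RSV alone. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over all genes of a comparison, and the threshold was 0.05. Group levels are means ± SD of TPM over the libraries of a group.

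There were 42 gene lists, of which 39 had at least 3 tested members. The others were the epithelial and B cell markers, with 2 tested members each, of which 1 B cell marker fell with RSV and 0 passed otherwise, and the erythroid and platelet markers, with 0 tested. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and the rotation test fry were run beside it. Fry asks whether the genes of a list move one way on balance, and does not compare them with other genes. It passed for 27, 0, 27 and 27 lists in the 4 comparisons in the order above. Among the lists described that missed the camera threshold it passed for the proteases (adjusted p = 0.00025), the receptors and attachment factors (0.0054) and the interferons and their receptors (4.8e-05) with RSV. For sivelestat against rhCTSC it passed for the inflammatory cytokines (0.0073), the lysosomal genes (0.00053), the monocyte markers (0.00035), the receptors and attachment factors (0.00053) and the coagulation genes (1.2e-05).

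The genes named are drawn from those a fixed rule takes. It takes CTSC, PRTN3, ELANE and CTSG in every comparison. It adds the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 TPM in the higher group, libraries that do not overlap between the groups and an approved symbol. It adds up to 3 members of each list past the threshold with the largest changes. Where fewer than 5 genes pass, it adds the 5 smallest p-values. Exceptions are named as chosen after their values were seen. The text names only part of the genes the rule takes, picked after their values were seen, and for sivelestat against RSV only a few. The others are not reported here. The lists described for each comparison were picked among the 42 after their values were seen, and some whose sign changed between alternatives were left out. The grouping, the tests, the lists, this rule and the alternatives other than 1 were chosen before the data were examined.

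Comparisons that share libraries were set against each other through the covariance of their log2 changes, beside 1000 simulated draws of unchanged groups made from the residuals. The fitting was tested on simulated data, in which 230 of 12284 genes were changed by known amounts. For RSV against PBS, 80% of genes changed by 1 on the log2 scale and 36% of those changed by 0.5 were recovered, with 8 false among 135 calls. For rhCTSC with RSV against RSV the shares were 88% and 46%, with 13 false among 162 calls. For sivelestat against rhCTSC they were 88% and 35%, with 4 false among 141. For sivelestat against RSV they were 87% and 38%, with 9 false among 147.

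The alternatives were a pseudocount of 0.1, no filter, a filter at 5 TPM in at least 2 libraries, median-of-ratios scaling, quantile normalization, a fit to only the 2 groups compared, library weights, the replicate number as a block, a 2-fold minimum, and each library left out in turn. Where this left 1 library in a group, its spread was taken to be that of the other groups. Leaving out the second libraries of the RSV and rhCTSC groups together was added after seeing the data. Figures were drawn with matplotlib 3.10.9.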

Results

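Gene expression was measured by mRNA sequencing in THP-1 cells, a human monocytic leukaemia line that turns into macrophage-like cells under the phorbol ester PMA, here given at 200 nM for 48 h. The infected cells had received respiratory syncytial virus (RSV), an RNA virus of the airways, at a multiplicity of infection of 5 for 24 h. Before infection some cells were held for 24 h with recombinant human cathepsin C (rhCTSC), the lysosomal dipeptidyl peptidase that activates neutrophil elastase, cathepsin G and proteinase 3. Others received rhCTSC together with sivelestat, known as an inhibitor of neutrophil elastase and described in the labels as an inhibitor of proteinase 3. The doses of rhCTSC and sivelestat are not given in the sources used here. The 10 libraries analysed form 4 groups: PBS (buffer) with 2 libraries, RSV with 3, rhCTSC with RSV with 3, and rhCTSC with sivelestat and RSV with 2. PBS replicate 1 and replicate 3 of the sivelestat group were not analysed here. No group had sivelestat alone or rhCTSC without virus.

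Each library was given as TPM, each gene's share of the transcripts scaled to a fixed total, over 20344 genes. TPM keeps no sequencing depth, so the depth is unknown. Between 11224 and 11678 genes reached 1 TPM per library. Pearson's r of log2(TPM + 1) across genes was 0.987 to 0.993 within groups. Between the RSV and the rhCTSC with RSV libraries it spanned 0.987 to 0.993 as well. The first principal component held 65.4% of the variance and parted the PBS libraries from the infected ones, and the second, with 22.7%, parted the sivelestat libraries from the rest. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

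**Figure D1:**
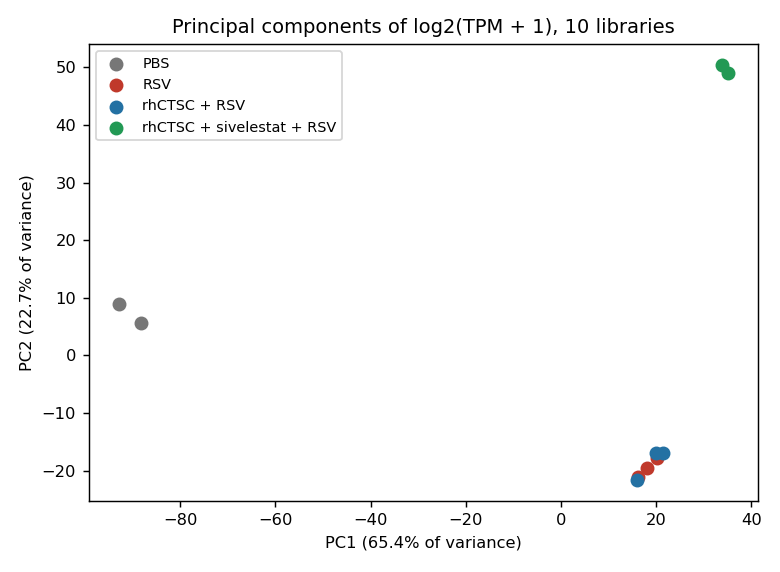
Principal components 1 (x axis, 65.4% of the variance) and 2 (y axis, 22.7%) of log2(TPM + 1), with 1 point per library coloured by group. The RSV and rhCTSC with RSV libraries overlie each other, while the 2 PBS libraries and the 2 sivelestat libraries each stand apart.

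The RSV group was first compared with the PBS group, which asks how PMA-treated THP-1 cells given the virus differ from those given buffer. Because the control received buffer, anything given along with the virus cannot be told apart from the infection. Cytokine transcripts rose by the widest margins. TNF, a cytokine that starts inflammatory responses, went from 15.8 ± 10.3 TPM (SD, n = 2) to 5062 ± 588 TPM (n = 3), a log2 change of 8.38 (SE 0.28, limma adjusted p = 4.0e-09). IL1B, a pyrogenic cytokine, went from 266 ± 106 to 37450 ± 2479 TPM (log2 change 7.19) and was the most abundant transcript of every infected library. The neutrophil-attracting chemokine CXCL8 reached 24480 ± 917 TPM from 156 ± 64.3 TPM (7.35). IL23A, a subunit of interleukin 23, had the largest log2 change of the genes named by the fixed rule, at 8.98, from 2.66 ± 0.25 to 1854 ± 176 TPM. IL1A (8.28), CSF2 (8.28), CCL1 (8.18) and IL6 (7.65) rose in the same way. IL12B was listed at 0 in both PBS libraries and averaged 206 ± 9.32 TPM in the RSV group.

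All 20 tested NF-kB feedback genes, targets that the transcription factor NF-kB induces, rose with RSV (20 adjusted over the list alone). Their median log2 change was 3.64, with BIRC3 at 5.94, TRAF1 at 5.79 and PTGS2, the inducible prostaglandin synthase, at 5.61. The list's camera test gave an adjusted p of 6.5e-22, and an adjusted p of 0.0639 with an estimated correlation. Of 19 tested inflammatory cytokines 16 rose and 1 fell (16 and 2 adjusted over the list alone), with a median of 4.28. The camera adjusted p was 5.5e-12, and adjusted p = 0.0639 with an estimated correlation. Of 19 chemokines 15 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 5.04 and CXCL2 at 7.22. Their adjusted p was 2.2e-11, and adjusted p = 0.0863 with an estimated correlation. Genes of M1 polarization, the inflammatory macrophage state, rose in 11 of 18 cases and fell in 3 (13 and 3 adjusted over the list alone), with a median of 4.29. That list gave adjusted p = 2.5e-08, and adjusted p = 0.0639 with an estimated correlation.

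Genes of glycolysis and hypoxia rose with RSV in 19 of 27 cases and fell in 3 (19 and 3 adjusted over the list alone). The growth factor VEGFA rose by a log2 change of 2.37, hexokinase HK2 by 1.93 and the glucose transporter SLC2A1 by 1.84. The list's median change was 0.38 (adjusted p = 4.8e-07), and it was the only list of this comparison to pass with an estimated correlation (adjusted p = 0.0446). Of 17 genes of the ATF4 amino acid response 11 rose and 1 fell (11 and 1 adjusted over the list alone), led by the cystine transporter SLC7A11 (4.42), with adjusted p = 2.4e-05 and adjusted p = 0.0652 with an estimated correlation. Of 13 serine protease inhibitors 9 rose and 2 fell (9 and 2 adjusted over the list alone), with TFPI2 at 5.61 and SERPINB9, an inhibitor of granzyme B, at 4.50 (adjusted p = 0.00033, and adjusted p = 0.0639 with an estimated correlation). All 5 tested metallothioneins, metal-binding proteins, rose (5 adjusted over the list alone), with MT2A at 2.52 (adjusted p = 0.0012, and adjusted p = 0.0639 with an estimated correlation). Of 16 NRF2 antioxidant genes 11 rose and 4 fell (11 and 5 adjusted over the list alone), among the latter haem oxygenase HMOX1 at -2.53 (adjusted p = 0.0011, and adjusted p = 0.278 with an estimated correlation).

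Macrophage genes fell with RSV. TREM2, a lipid-sensing receptor of macrophages, went from 626 ± 15.4 TPM (n = 2) to 9.01 ± 2.14 TPM (n = 3), a log2 change of -5.99 (SE 0.23, limma adjusted p = 8.6e-09). The fatty acid-binding protein FABP4 went from 1263 ± 514 to 20.6 ± 9.71 TPM (-5.90), and the amino acid transporter SLC7A8 from 104 ± 13.3 to 0.398 ± 0.235 TPM (-6.23). DDIT4L (-5.33), the adenosine receptor ADORA3 (-5.19), MTUS1 (-5.01), the leukotriene receptor CYSLTR1 (-4.98) and NRGN (-4.83) completed the 8 largest falls of the fixed rule. Of 14 tested macrophage markers 12 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -2.16 and the scavenger receptor MSR1 at -4.58. The camera adjusted p was 0.00014, and adjusted p = 0.0689 with an estimated correlation. Monocyte markers fell in 5 of 8 cases (5 adjusted over the list alone), including CD36 (-4.18), CD14 (-2.42) and lysozyme LYZ (-1.73), with adjusted p = 0.0294 and adjusted p = 0.222 with an estimated correlation.

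Lysosomal genes and genes of lipid handling were also lower in the RSV group. Of 22 lysosomal cathepsins and hydrolases 14 fell and 4 rose (15 and 4 adjusted over the list alone), with acid lipase LIPA at -3.35, CTSD at -2.82 and CTSL at -2.54. The list's adjusted p was 0.0061, and adjusted p = 0.222 with an estimated correlation. Of 17 genes of cholesterol efflux and lipid handling 13 fell and 2 rose (13 and 2 adjusted over the list alone), with the lipid droplet protein PLIN2 at -3.41 (adjusted p = 0.0095, and adjusted p = 0.381 with an estimated correlation). Of 17 genes of the unfolded protein response 12 fell and 3 rose (12 and 3 adjusted over the list alone), with the chaperones PDIA4 at -1.85 and HSP90B1 at -1.59. This list had adjusted p = 0.0382, adjusted p = 0.411 with an estimated correlation, adjusted p = 0.0535 with the filter at 5 TPM, and adjusted p = 0.0507 without RSV replicate 3.

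The endogenous transcripts of the proteases under study fell with RSV. CTSC itself (chromosome 11, 88293592 to 88337787, GRCh38) went from 485 ± 43.8 TPM (n = 2) to 138 ± 11.5 TPM (n = 3), a log2 change of -1.81 (SE 0.08, limma adjusted p = 3.6e-08). CTSG, which encodes cathepsin G (chromosome 14, 24573522 to 24576260), went from 632 ± 58.9 to 125 ± 50.4 TPM (-2.41). PRTN3, which encodes proteinase 3 (chromosome 19, 840960 to 848175), went from 298 ± 16.2 to 67.8 ± 27.8 TPM (-2.20). ELANE, which encodes neutrophil elastase and lies next to PRTN3 (chromosome 19, 851014 to 856247), went from 353 ± 18.3 to 87.0 ± 31.5 TPM (-2.07). Of the 7 tested members of the protease list 6 fell and 1 rose (6 and 1 adjusted over the list alone), and as a set they missed the threshold (adjusted p = 0.0899). The set passed under median-of-ratios scaling (adjusted p = 0.0383), under quantile normalization (0.0225), with the filter at 5 TPM (0.0239) and without the second libraries of the RSV and rhCTSC groups (0.0175).

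Interferon-stimulated genes, the usual antiviral program, did not rise as a group. Of 53 tested members 2 rose and 9 fell (2 and 3 adjusted over the list alone), with a median of -0.57 and adjusted p = 0.755. LAMP3 rose by 6.76 and GBP5 by 2.08, both also known to respond to inflammatory signals. The macrophage lectin SIGLEC1 changed by -1.33 (limma adjusted p = 0.0214), a call that was lost without PBS replicate 3 (0.177), RSV replicate 1 (0.0683) or RSV replicate 3 (0.0561). The mean log2 level of the list differed widely within groups, at 5.70 and 6.51 in the PBS libraries and 5.18, 6.31 and 5.90 in the RSV libraries.

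In total 2222 genes rose and 4544 fell of 12284 tested (limma with Benjamini-Hochberg adjustment), 731 and 1731 of them by at least 2-fold. The median log2 change of all genes was -0.17, so the split depends on the scaling: it was 3264 higher and 3476 lower under median-of-ratios scaling, and 3434 and 3304 under quantile normalization. Of 39 lists tested 11 moved up and 5 down by camera.

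**Figure D2:**
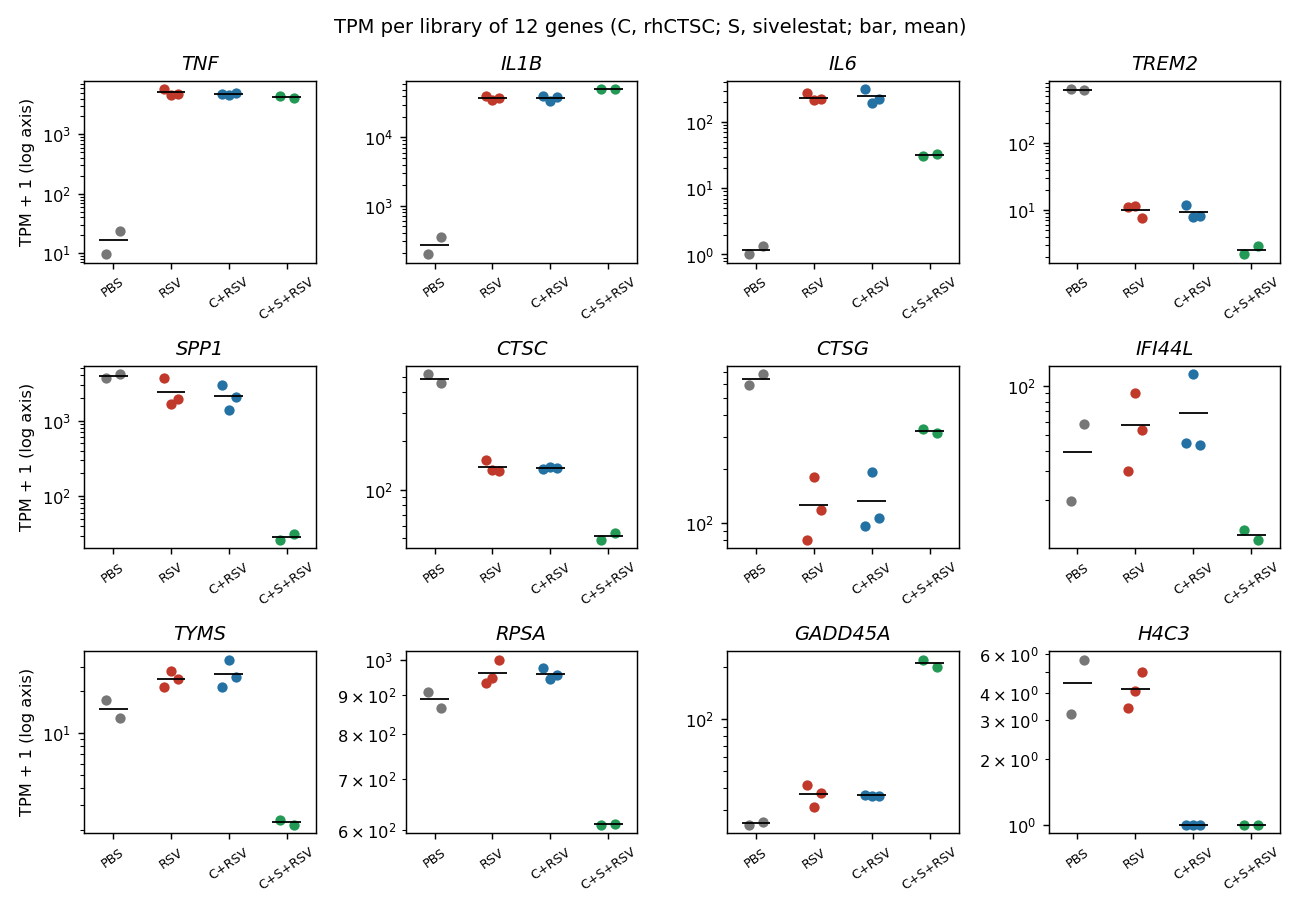
TPM + 1 (y axis, log scale with its own range in each panel) of 12 genes, with 1 point per library in the 4 groups and a bar at the group mean. TNF, IL1B and IL6 are high in all infected groups against PBS, IL6 and SPP1 are lower with sivelestat, and H4C3 is listed at 0 in all 5 libraries with rhCTSC.

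The rhCTSC with RSV group was then compared with RSV alone, which asks what cathepsin C given as a protein before infection does to the response. Few differences were found. IL1B stood at 37450 ± 2479 TPM with RSV and 37610 ± 2975 TPM with rhCTSC (n = 3 each, log2 change 0.01), and TNF at 5062 ± 588 and 4794 ± 226 TPM (-0.07). These 2 genes lie outside the naming rule for this comparison and were chosen after their values were seen. The endogenous CTSC transcript had a log2 change of -0.02 (138 ± 11.5 and 135 ± 2.12 TPM), PRTN3 0.07 (67.8 ± 27.8 and 71.0 ± 29.4), ELANE -0.06 (87.0 ± 31.5 and 83.5 ± 31.6) and CTSG 0.07 (125 ± 50.4 and 130 ± 52.6). None of these 6 genes passed the test (limma adjusted p = 0.999 for each).

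In this comparison 0 genes rose and 2 fell of 12284, and 369 had an unadjusted p under 0.05 (limma). Both that fell are histone genes. H4C3, a histone H4 gene (chromosome 6, 26103876 to 26104310), averaged 3.17 ± 0.79 TPM in the RSV group and was listed at 0 in all 3 rhCTSC libraries (adjusted p = 0.0148). H2AC20, a histone H2A gene (chromosome 1, 149886975 to 149887364), went from 2.61 ± 0.56 to 0.183 ± 0.159 TPM (log2 change -1.61, adjusted p = 0.0148). The next smallest p-values did not pass: H2AC21 (1.24 ± 0.45 TPM with RSV and listed at 0 with rhCTSC, adjusted p = 0.449), H4C5 (1.71 ± 0.24 and 0.315 ± 0.028 TPM, 0.666) and ZNF559-ZNF177 (0.245 ± 0.269 and 1.27 ± 0.036 TPM, 0.808). Histone genes have near-identical copies among which reads can be divided, so their single values are uncertain. The call of H4C3 was lost without any 1 library of the RSV, rhCTSC or sivelestat groups (adjusted p up to 0.116), and that of H2AC20 without any 1 library other than rhCTSC replicate 3 (up to 0.116). H4C3 did not pass with no filter (0.0554), nor H2AC20 with a pseudocount of 0.1 (0.183), only the 2 groups in the fit (0.129) or the replicate number as a block (0.117). Neither passed without the second libraries of both groups (0.494 and 0.398).

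The 10 replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail and which were fixed as a sign of poly(A) selection, had a median log2 change of -0.25 with rhCTSC (-0.32 to -0.11 with single libraries left out), with 0 risen and 1 fallen (0 and 2 adjusted over the list alone). The camera adjusted p was 8.6e-05, adjusted p = 0.715 with an estimated correlation, 0.989 by limma's rotation test fry, 0.281 with the filter at 5 TPM, and 0.0882 without the second libraries of both groups. Libraries with and without rhCTSC also differed in traces of fibroblast transcripts: COL1A2, COL3A1 and DCN, 3 of the 10 fibroblast markers fixed as signs of another cell type, were above 0 in all 5 libraries without rhCTSC and listed at 0 in all 5 with it. Their means without rhCTSC were 0.715, 0.185 and 0.344 TPM. The number of genes listed at 0 was 5646 to 5770 without rhCTSC and 5910 to 5959 with it.

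Mitochondrially encoded mRNAs (median log2 change -0.08, adjusted p = 0.0181) and genes of cholesterol efflux and lipid handling (-0.14, adjusted p = 0.0348) were the other lists past the camera threshold, with 0 members of either past the gene test, over all genes or adjusted over the list alone. With an estimated correlation they had adjusted p = 0.715 and adjusted p = 0.778, and by fry 0.989 each. The call for the mitochondrial mRNAs was lost without RSV replicate 1 (median -0.051, adjusted p = 0.181), RSV replicate 3 (0.0530) or rhCTSC replicate 2 (-0.034, 0.421), and that for lipid handling without RSV replicate 1 (-0.0092, 0.902) or rhCTSC replicate 2 (-0.028, 0.570). Both were lost with no filter (0.112 and 0.0775), under median-of-ratios scaling (0.0617 each) and under quantile normalization (0.479 and 0.0564). Both were also lost without the second libraries of the RSV and rhCTSC groups (0.135 and 0.129), and lipid handling with library weights (0.122). The 20 NF-kB feedback genes had a median of -0.03 and the 53 interferon-stimulated genes a median of 0.08, with 0 members of either past the test. Single libraries set the sign of the latter: its median was -0.20 without RSV replicate 1 (camera adjusted p = 3.0e-05), -0.21 without rhCTSC replicate 2 (0.0020), 0.31 without RSV replicate 2 (3.9e-07) and 0.18 without rhCTSC replicate 3 (0.0083). The 25 cell cycle genes had a median of 0.02, which was -0.13 without rhCTSC replicate 2 (0.0438).

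The 95% intervals of the log2 changes, taken gene by gene without adjustment, show how precisely these libraries were compared. They do not bound an effect of rhCTSC on the cells, since the spread between these libraries may be technical. Among the 7734 genes at 10 TPM or more in either group the median half-width of the 95% interval was 0.22 on the log2 scale, and for 99.4% of them the interval lay within 1 of 0. In simulated data for this comparison, with 230 of 12284 genes changed, 88% of genes changed by 1 on the log2 scale and 46% of those changed by 0.5 were recovered. The adjusted threshold is stricter where fewer genes change, so these shares overstate what would be recovered if rhCTSC changed only a few genes.

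Next, the libraries with rhCTSC, sivelestat and RSV were compared with those with rhCTSC and RSV, which asks what the protease inhibitor changes. The sample titles name no solvent control for sivelestat, so anything given along with it cannot be told apart from the inhibitor. SPP1, which encodes the macrophage-secreted osteopontin, fell from 2138 ± 798 TPM (n = 3) to 27.9 ± 3.37 TPM (n = 2), a log2 change of -6.15 (SE 0.34, limma adjusted p = 9.2e-07). IL1RN, the natural antagonist of the interleukin 1 receptor, fell from 625 ± 196 to 23.6 ± 3.87 TPM (-4.62). The matrix metalloproteinases MMP9 (-4.32) and MMP7 (-4.23), the activin subunit INHBA (-4.13), PINLYP (-3.96), MSR1 (-3.94) and RGS1 (-3.82) also fell. Among the rises, PHF19, a Polycomb accessory protein, went from 8.08 ± 0.80 to 88.4 ± 1.92 TPM (3.30), and the stress-induced GADD45A from 35.3 ± 0.26 to 210 ± 13.9 TPM (2.54). The scaffold protein AKAP12 (3.25), SNN (2.51), MMP10 (2.50), TPBG (2.44) and carboxylesterase CES1 (2.41) rose as well.

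The inflammatory transcripts did not move together with sivelestat. IL6 fell from 243 ± 61.0 to 30.5 ± 1.67 TPM (log2 change -2.93), and OSM by a change of -2.39. Of 19 inflammatory cytokines 5 rose and 7 fell (5 and 7 adjusted over the list alone), with adjusted p = 0.417 for the set. IL1B, outside the naming rule here and chosen after its value was seen, stood at 37610 ± 2975 and 50420 ± 196 TPM (0.43, limma adjusted p = 0.0923). It passed without PBS replicate 2 (0.0037) or PBS replicate 3 (0.0035) or with only the 2 groups in the fit (0.0343), and its change was 0.00 under quantile normalization, because it is the top gene of both groups. Of 19 chemokines 11 fell and 3 rose (13 and 3 adjusted over the list alone), among them the monocyte attractant CCL2, from 1191 ± 51.4 to 156 ± 8.52 TPM (-2.92), CCL1 (-3.58) and CCL7 (-3.12). Their median was -1.13, with adjusted p = 0.0073 and adjusted p = 0.498 with an estimated correlation. Of 20 NF-kB feedback genes 6 rose and 3 fell (6 and 3 adjusted over the list alone), with NFKBIZ at 1.39, BCL2A1 at 0.98 and the NF-kB inhibitor NFKBIA at 0.84 (adjusted p = 0.195 for the set).

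Cell cycle genes fell with sivelestat in 22 of 25 cases and rose in 0 (22 and 0 adjusted over the list alone), with a median of -1.50. Thymidylate synthase TYMS went from 25.8 ± 6.45 to 1.27 ± 0.14 TPM (-3.53), the ribonucleotide reductase subunit RRM2 had a log2 change of -3.06 and thymidine kinase TK1 one of -2.96. The camera adjusted p was 1.6e-09, and adjusted p = 0.251 with an estimated correlation. Ribosomal protein genes fell by less but as regularly, in 27 of 31 cases (28 adjusted over the list alone) with a median of -0.43, RPSA at -0.65 and RPL3 at -0.64 (adjusted p = 1.6e-09, and adjusted p = 0.251 with an estimated correlation). Of 22 nuclear genes of oxidative phosphorylation 12 fell and 0 rose (12 and 0 adjusted over the list alone), with the ATP synthase subunit ATP5F1A at -0.61 (adjusted p = 0.0047, and adjusted p = 0.251 with an estimated correlation). Of 27 glycolysis and hypoxia genes 15 fell and 3 rose (15 and 3 adjusted over the list alone), with PFKFB4 at -2.11 and VEGFA at -2.05 (adjusted p = 0.0057, and adjusted p = 0.127 with an estimated correlation). Of 17 ATF4 genes 9 fell and 1 rose (9 and 1 adjusted over the list alone), with the amino acid transporter SLC7A5 at -2.12 and the transcription factor CEBPB at -1.70 (adjusted p = 0.0140, and adjusted p = 0.251 with an estimated correlation).

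Macrophage markers fell in 13 of 14 cases (14 adjusted over the list alone), with a median of -1.83 (adjusted p = 3.0e-08, and adjusted p = 0.127 with an estimated correlation). Of 17 Fc receptor and phagocytosis genes 11 fell and 2 rose (11 and 2 adjusted over the list alone), with the oxidase subunit CYBB at -3.59 and the Fc receptor chain FCER1G at -2.88 (adjusted p = 0.0057, and adjusted p = 0.127 with an estimated correlation). Of 17 lipid handling genes 10 fell and 2 rose (12 and 4 adjusted over the list alone), with FABP4 at -3.02 and lipoprotein lipase LPL at -2.64 (adjusted p = 0.0061, and adjusted p = 0.326 with an estimated correlation). Of 15 M2 polarization genes 8 fell and 2 rose (9 and 2 adjusted over the list alone), with CCL22 at -2.69 and TGM2 at -2.02 (adjusted p = 0.0148, and adjusted p = 0.230 with an estimated correlation). That list had adjusted p = 0.0807 with no filter on low values. Monocyte markers fell in 4 of 8 cases (5 fell and 1 rose adjusted over the list alone), with CD36 at -3.18, and missed the threshold as a set (adjusted p = 0.0989). Of 22 lysosomal genes 9 fell and 5 rose (9 and 5 adjusted over the list alone), with CTSH at -2.08, CTSL at -1.92 and CTSD at -1.79 (adjusted p = 0.240 for the set).

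Interferon-stimulated genes fell with sivelestat in 28 of 53 cases and rose in 0 (32 and 0 adjusted over the list alone), with a median of -1.06. The chemokine CXCL10 went from 33.4 ± 10.3 to 6.50 ± 2.25 TPM (-2.19), and IFI44L had a log2 change of -2.33, a call lost without sivelestat replicate 2 (adjusted p = 0.0519). The list's camera adjusted p was 9.1e-06, adjusted p = 0.607 with an estimated correlation, and 0.0888 by fry. Genes of apoptosis and necroptosis rose in 10 of 19 cases and fell in 0 (11 and 0 adjusted over the list alone), with BCL2L11, which encodes the death-promoting protein BIM, at 1.18, the death receptor TNFRSF10B at 1.06 and PMAIP1 at 0.95 (adjusted p = 0.0058, and adjusted p = 0.127 with an estimated correlation). The inflammatory caspase CASP1 fell, with a log2 change of -1.39.

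The replication-dependent histone genes, fixed as a possible sign of poly(A) selection, were higher with sivelestat while the cell cycle genes fell. The histone median was 1.02, with 6 of 10 rising and 0 falling (7 and 0 adjusted over the list alone), with H2BC4 at 1.90, H2BC5 at 1.41 and H1-2 at 1.36 (adjusted p = 0.0026, and adjusted p = 0.251 with an estimated correlation). H2AC19 was listed at 0 in the other 8 libraries and at 44.5 and 93.8 TPM in the sivelestat libraries. Its near-identical copy H2AC18 stood at 211 and 131 TPM there and at 113 to 130 TPM in the RSV and rhCTSC libraries, so the division of reads between the copies leaves the value of H2AC19 uncertain. The summed TPM of all 17 H2A genes was 311 and 276 in the sivelestat libraries. It was 150 to 161 in the RSV libraries and 144 to 155 in the rhCTSC libraries. Division of reads within the family would not give this rise of the sum.

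Of the proteases, CTSC fell further with sivelestat, from 135 ± 2.12 to 50.6 ± 3.46 TPM (log2 change -1.41, SE 0.08, limma adjusted p = 1.4e-06). CTSG rose from 130 ± 52.6 to 325 ± 13.9 TPM (1.38, adjusted p = 0.0065). ELANE went from 83.5 ± 31.6 to 148 ± 27.3 TPM (0.87, adjusted p = 0.0385), a call lost without RSV replicate 3 (0.0538), rhCTSC replicate 1 (0.104) or 3 (0.101), or sivelestat replicate 1 (0.223) or 2 (0.0694), or with no filter (0.0796). PRTN3 stood at 71.0 ± 29.4 and 124 ± 9.07 TPM (0.87, adjusted p = 0.0596), and passed without RSV replicate 1 (0.0328) or 2 (0.0314) or rhCTSC replicate 2 (0.0112), under median-of-ratios scaling (0.0464) or quantile normalization (0.0371), with library weights (0.0214) and without the second libraries of the RSV and rhCTSC groups (1.18, 0.0015). Of the 7 list members 4 rose and 2 fell (5 and 2 adjusted over the list alone), with a median of 0.80 and adjusted p = 0.535 for the set, whose direction was up by camera and down by fry.

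In total 2364 genes rose and 2896 fell with sivelestat (limma), 298 and 829 of them by at least 2-fold. The split depends on the scaling, with 2978 higher and 2565 lower under quantile normalization. The count of 5260 was 3464 without sivelestat replicate 1. Of 39 lists 2 moved up and 11 down by camera, and 0 passed with an estimated correlation.

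**Figure D3:**
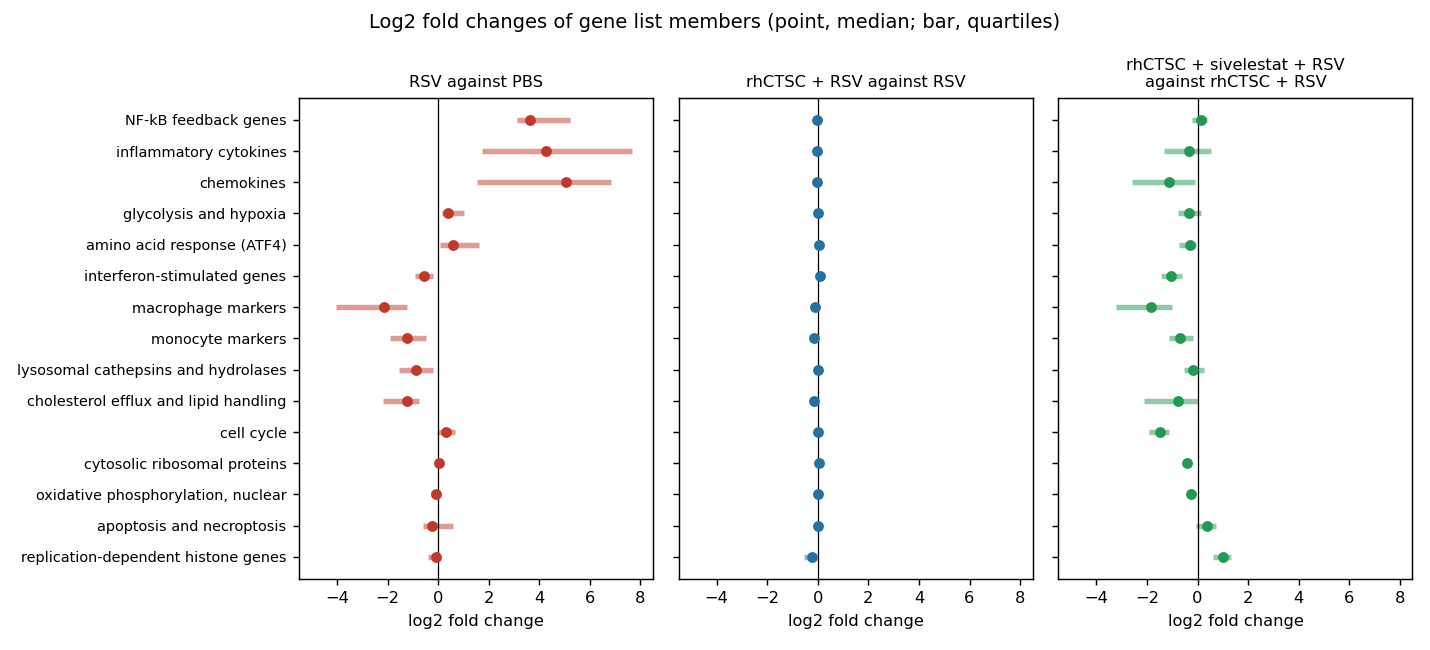
Log2 fold changes (x axis) of 15 gene lists (y axis) in 3 comparisons, with a point at the median over the tested members and a bar from the lower to the upper quartile. The NF-kB feedback genes have a median of 3.64 with RSV, -0.03 with rhCTSC and 0.12 with sivelestat, and the cell cycle genes one of -1.50 with sivelestat.

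The same sivelestat libraries were also compared with RSV alone, which sets the joint treatment against untreated infection. IL6 fell from 234 ± 31.1 to 30.5 ± 1.67 TPM (n = 3 and 2, log2 change -2.89, limma adjusted p = 3.1e-06), while IL23A rose from 1854 ± 176 to 6798 ± 111 TPM (1.88). SPP1 (-6.29), IL1RN (-4.81), MMP9 (-4.53) and the growth factor-binding protein IGFBP3 (-3.81) fell, and AKAP12 (3.23) and PHF19 (3.03) rose. TYMS had a log2 change of -3.43, CASP1 one of -1.21 and CXCL10 one of -2.23. CTSC changed by -1.43 and CTSG by 1.45. ELANE had a log2 change of 0.81 and missed the threshold (limma adjusted p = 0.0506), and passed without RSV replicate 2 (0.0119) or rhCTSC replicate 1 (0.0426) or 2 (0.0184), under median-of-ratios scaling (0.0413) or quantile normalization (0.0278), with the filter at 5 TPM (0.0486), only the 2 groups in the fit (0.0392) or library weights (0.0166), and without the second libraries of the RSV and rhCTSC groups (0.00060). PRTN3 had one of 0.94 (adjusted p = 0.0441), a call lost without either PBS library (0.0554 and 0.0552), RSV replicate 1 (0.123) or 3 (0.0915), rhCTSC replicate 3 (0.0570) or either sivelestat library (0.180 and 0.118), or with no filter (0.0883).

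All 14 macrophage markers fell against RSV alone (14 adjusted over the list alone), with a median of -1.96 (adjusted p = 1.3e-08, and adjusted p = 0.114 with an estimated correlation). Cell cycle genes fell in 22 of 25 cases (22 adjusted over the list alone, adjusted p = 5.6e-09, and adjusted p = 0.289 with an estimated correlation) and ribosomal protein genes in 27 of 31 (27 adjusted over the list alone, adjusted p = 1.1e-08, and adjusted p = 0.289 with an estimated correlation). Of 53 interferon-stimulated genes 24 fell (24 adjusted over the list alone, adjusted p = 4.1e-05, adjusted p = 0.619 with an estimated correlation, and 0.113 by fry). Of 3 tested fibroblast markers 2 fell (3 adjusted over the list alone), COL6A3 from 35.4 ± 5.32 to 2.12 ± 0.44 TPM and PDGFRA with a log2 change of -1.49 (adjusted p = 0.0385 for the set, adjusted p = 0.286 with an estimated correlation, 0.0526 without rhCTSC replicate 1, 0.0511 with only the 2 groups in the fit, and 0.0586 with library weights). COL6A3 was high in the RSV and rhCTSC libraries alike, unlike the collagens COL1A2 and COL3A1. In total 2452 genes rose and 2894 fell (limma), 313 and 857 by at least 2-fold, beside 3074 higher and 2573 lower under quantile normalization, and the count of 5346 was 3525 without sivelestat replicate 1.

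The changes were last set against each other across genes, which are not independent replicates. The rhCTSC and sivelestat comparisons share the rhCTSC libraries, so chance alone makes their changes run against each other. Their Pearson correlation was -0.064, beside -0.416 in simulated unchanged groups (95% of draws from -0.899 to 0.413). These correlations are not comparable, since the many changes with sivelestat draw the observed one toward 0, so the covariances were compared. The covariance was -0.0064 and the simulated one -0.0152, a difference of 0.0088 that is smaller than the SD between draws of 0.0159. For the RSV and rhCTSC comparisons, which share the RSV libraries, the covariance was -0.0057 beside -0.0156, a difference of 0.0098 with an SD between draws of 0.0171. Neither of the 2 genes that fell with rhCTSC rose with sivelestat, since H4C3 and H2AC20 were listed at 0 in both sivelestat libraries. The RSV and sivelestat comparisons share no library, and their changes had a Pearson correlation of -0.034. Of the 2222 genes that rose with RSV 823 fell with sivelestat, beside 524 for independent lists of these sizes, and 453 rose further, beside 428. Of the 4544 that fell with RSV 921 rose with sivelestat, beside 874.5, and 1005 fell further, beside 1071.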

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

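Most results kept their direction and their side of the threshold under the alternatives: 1053 of the single-gene values for RSV against PBS, with 3 losing their call, and 1211 for sivelestat against rhCTSC, with 9 losing and 12 gaining one. For rhCTSC against RSV, 165 kept both, 23 lost their call and 16 changed sign. The 23 lost calls all belong to H4C3 and H2AC20, the only genes of that comparison with a call to lose. All these tallies are over the genes the text names, a set cut down after some of these values were seen. The count of genes past the threshold for RSV against PBS was 2462 with a 2-fold minimum. That for sivelestat against rhCTSC was 1127 with a 2-fold minimum and 3464 to 5263 with single libraries left out, and that against RSV alone 1170 and 3525 to 5833. A 2-fold minimum lets fewer genes qualify. The cause of the changes with libraries left out, rises among them, was not tested. For rhCTSC against RSV the count of 2 was 1 with a pseudocount of 0.1, with no filter, with only the 2 groups compared and with the replicate block, 0 with the filter at 5 TPM, which removes both genes, and 0 without both second libraries (chosen after seeing the data). It was 0 to 3 with single libraries left out, where the 3 without rhCTSC replicate 3 share 1 gene with the count of 2. The cause was not tested beyond this.

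Signs changed mainly where values were near 0. For rhCTSC against RSV, library weights gave log2 changes of 0.0044 for CTSC, -0.0010 for CTSG, 0.0037 for the NF-kB feedback genes and -0.023 for the interferon-stimulated genes. IL1B had -0.0062 under median-of-ratios scaling and 0.00 under quantile normalization, and 0.00 too for sivelestat against rhCTSC. The cell cycle genes had -0.080 without both second libraries. Leaving out single libraries gave -0.063 to 0.044 for CTSC, -0.24 to 0.37 for PRTN3, -0.35 to 0.21 for ELANE, -0.24 to 0.37 for CTSG, -0.044 to 0.072 for IL1B and -0.14 to 0.019 for TNF. It gave -0.061 to 0.013 for the NF-kB feedback genes, -0.21 to 0.31 for the interferon-stimulated genes and -0.13 to 0.18 for the cell cycle genes. For RSV against PBS, the median of the viral RNA sensing genes was 0.097 under median-of-ratios scaling and 0.077 under quantile normalization. That of the RSV receptors was -0.042 with the replicate block and -0.19 to 0.45 with single libraries left out. The cause was not tested for these.

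The replicate numbers were not taken to pair the samples: deviations from the group means of same-numbered RSV and rhCTSC libraries correlated across genes at 0.19, 0.33 and -0.01, and those of RSV replicate 3 were not closest to its own number, although its levels were (Pearson's r 0.9926). As a hint the other way, the third principal component was alike by number (-13.3, 12.2 and -0.12 with RSV, -16.8, 18.01 and -1.4 with rhCTSC). With the number as a block the counts were 6462, 1, 4868 and 4979 for RSV against PBS, rhCTSC against RSV, and sivelestat against rhCTSC and against RSV. H2AC20 had adjusted p = 0.117 with the block for rhCTSC against RSV, and IL1B (0.50, adjusted p = 0.0407) and PRTN3 (0.0338) passed for sivelestat against rhCTSC, where 1 monocyte marker rose. The covariance differences were 0.0083 and 0.0097 with the block, and 0.0018 to 0.0127 and 0.0016 to 0.0157 with single libraries left out. A fit to only 2 groups gives no covariance. The unknown depth limits what can be said of genes near 0 TPM.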

Other observations

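Of the tests below, those of scaling and of summed H4 and H2A transcripts were chosen before the values they measure were seen, and the others after.

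Genes by which RSV attaches or enters moved apart. Of 11 tested receptors and attachment factors 5 rose with RSV and 5 fell (5 and 5 adjusted over the list alone). EGFR went from 0.582 ± 0.330 TPM in the PBS group to 8.12 ± 0.74 TPM in the RSV group (log2 change 2.54) and the heparan sulfate proteoglycan SDC4 from 20.3 ± 3.78 to 116 ± 7.45 TPM (2.47). The chemokine receptor CX3CR1 fell from 13.2 ± 4.57 to 0.263 ± 0.085 TPM (-3.45). The list's median was 0.10 (adjusted p = 0.272), and -0.19 without RSV replicate 1. With sivelestat EGFR rose again, to 29.1 ± 0.89 TPM (1.80 against rhCTSC), as did EXT1, an enzyme of heparan sulfate synthesis (1.35), and of the 11 genes 5 rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.0989). Among 16 genes of viral RNA sensing and nearby pathways 4 rose and 7 fell with RSV (4 and 7 adjusted over the list alone): the DNA sensor CGAS rose by 1.33, while its adaptor STING1 changed by -2.63 and TLR4 by -1.67. Their median was -0.08, and 0.10 and 0.08 under median-of-ratios scaling and quantile normalization, while camera gave the direction as up (adjusted p = 0.755). Of 5 tested interferon and interferon receptor genes 1 rose and 2 fell (1 and 3 adjusted over the list alone), among them the interferon gamma receptor IFNGR1 at -1.88 (adjusted p = 0.489 for the set).

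Some clotting genes and 3 MHC class II genes also changed. Of 10 coagulation and fibrinolysis genes 8 rose and 1 fell with RSV (8 and 1 adjusted over the list alone, adjusted p = 0.0012, and adjusted p = 0.0639 with an estimated correlation), with the plasminogen activator PLAT from 0.079 ± 0.017 to 29.2 ± 3.53 TPM (4.80). With sivelestat 7 of the 10 fell and 3 rose (7 and 3 adjusted over the list alone, adjusted p = 0.102), with THBD at -2.21 and PLAT at -2.09. Immediate early genes rose with RSV in 11 of 20 cases and fell in 5 (11 and 5 adjusted over the list alone), with the phosphatase DUSP1 at 2.64 and the transcription factor KLF4 at -4.24. That list's adjusted p was 0.0103, with adjusted p = 0.411 with an estimated correlation, 0.0665 by fry, 0.10 with the filter at 5 TPM and 0.0709 under quantile normalization. Of 7 MHC class II genes 3 rose with sivelestat and 0 fell (3 and 0 adjusted over the list alone, adjusted p = 0.195): HLA-DQB1 at 1.15, HLA-DRB5 at 0.87 and HLA-DRB1 at 0.72. The limma call of HLA-DRB5 was lost without sivelestat replicate 2 (adjusted p = 0.0754) and that of HLA-DRB1 without sivelestat replicate 1 (0.0541).

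With RSV the NF-kB feedback genes rose while the interferon-stimulated genes did not. Scaling by a few abundant genes is argued against, since under median-of-ratios scaling the upper quartile of the interferon-stimulated genes' log2 changes was -0.024. A rise of the list hidden by a single library is argued against too, since with each library left out in turn the highest median was -0.20. The size of the change did depend on single libraries, as the lowest median was -0.90. A candidate explanation is that interferon transcripts were nearly absent at the time sampled: of 20 type I and type III interferon genes 17 were listed at 0 in every library, and the highest mean in the RSV group was 0.186 TPM (IFNB1). All of them were listed at 0 in the PBS libraries too, although the interferon-stimulated list stood about as high there as with RSV. Whether interferon rose and ended before 24 h, or was held down by the virus, was not tested, and no viral transcripts were analysed here.

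The histone genes H4C3 and H2AC20 fell with rhCTSC, and the list of replication-dependent histone genes, which holds H4C3, passed by camera (adjusted p = 8.6e-05) but not with an estimated correlation (adjusted p = 0.715). Fewer cells in S phase is argued against for these 2 genes (log2 changes -2.04 and -1.61), since the cell cycle list had a median of 0.021 and one no lower than -0.13 with single libraries left out, but stays open for the smaller change of the histone list, whose medians then overlap with those of the cell cycle list (lowest minus highest -0.022). The summed TPM changed by -0.41 for all 15 H4 genes and by -0.078 for all 17 H2A genes, which leaves open whether reads were divided otherwise among the copies. The H4 sum went from 75.2 ± 8.53 to 56.5 ± 8.17 TPM with no overlap of libraries, a fall that division within the family would not give but short of the -0.5 set down against it, while the losses of H4C3 (3.17 TPM) and H2AC20 (2.43 TPM) are below the SDs of the sums in the RSV group (8.53 and 5.78 TPM). The small H2A change met what had been set down in favour of that explanation, and the test was set aside for its coarseness only after this value was seen. A difference in library preparation may also be the source and cannot be told apart from rhCTSC, since the lowest number of genes listed at 0 with rhCTSC exceeded the highest without it by 140, and 9 genes, including H4C3, H3C2, COL1A2, COL3A1 and DCN, were listed at 0 only in the 5 libraries with rhCTSC (1 gene the reverse, 10 in all, beside 9 for the highest of the other splits into 5 and 5). For the 2 genes past the threshold, 1 of the 10 splits of the 6 libraries, the real one, gave as many, the highest other gave 1, and 10 splits are too few for a share under 0.05.

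In total 5260 genes differed between the sivelestat and the rhCTSC libraries. A weaker RSV response as the whole cause is argued against, since the changes with sivelestat and those with RSV had a Pearson correlation of -0.034 across genes. Of the 4544 genes that fell with RSV 1005 fell further, which is below the 1071 for independent lists and adds nothing to that argument. A part stays open: 823 of the 2222 genes that rose with RSV fell with sivelestat, beside 524 for independent lists. Of those that fell with RSV 921 rose, beside 874.5. Scaling by a few abundant genes is argued against for the cell cycle list, whose upper quartile stayed at -1.12 under median-of-ratios scaling. That scaling moved the median log2 change of all genes only from -0.012 to 0.0049. Of the 5260 genes 5151 also passed under it, while the split of all calls into rises and falls depends on the scaling. The 8 tested monocyte markers did not rise as a set, with a median of -0.70 and an upper quartile of -0.18. Of them 0 rose over all genes, and 1 rose when adjusted over the list alone or with the replicate block. These few markers cannot settle whether the cells returned toward a monocyte state, since the macrophage markers fell in 13 of 14 cases, and it stays open. For the cell cycle and ribosomal protein genes, an undoing of changes made by rhCTSC is argued against. Their medians were 0.02 and 0.03 for rhCTSC with RSV against RSV. For the sivelestat group against RSV alone they were -1.45 and -0.40. An effect of sivelestat on the cells apart from rhCTSC, which the falls of cell cycle and ribosomal protein genes might reflect, stays open because no group had sivelestat without rhCTSC. The histone list fixed as a sign of poly(A) selection moved with these changes (median 1.02). Whether this reflects RNA selection in these libraries or a change in the cells was not tested.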
